A study of Drosophila melanogaster with 4 samples.

How the data were processed

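The series comprised 4 libraries of Drosophila S2 cells, 2 of 5'GRO-seq and 2 of GRO-seq. Per the labels' protocols, nuclei were run on with a bromouridine nucleotide, labelled RNA was immunoprecipitated, and for 5'GRO-seq uncapped ends were dephosphorylated before caps were removed, so that adapters joined to formerly capped ends. GRO-seq libraries were decapped and phosphorylated without that step.

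Start sites were called by the authors with the TSS mode of HOMER, per the file headers, separately for each library. Sites were 150 bp wide, at least 300 bp apart on a strand and centred on the highest tag pile-up. They had to pass an FDR of 0.001, exceed 4-fold and a p of 0.0001 over the GRO-seq library used as control, and exceed 4-fold over the surrounding 1000 bp. Per the file headers, the FDR required 20 reads in replicate 1 and 14 in replicate 2. The control removed 34739 of 42363 putative sites (82.0%) in replicate 1 and 38617 of 52131 (74.1%) in replicate 2; the local filter removed a further 842 and 4127. The lists hold intervals of 151 bp and a constant in the score column, so sites had no score. The submitters' processing notes name CASAVA 1.8.2, Bowtie2 2.1.0, HOMER 4.7 and the dm3 build, with no role or settings. Alignment settings are not given in the sources used here.

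GRO-seq values were deposited by the authors as FPKM, for 1 RefSeq transcript per gene in dm3. The column names, Sample3 and Sample4, carry no replicate number, so they were used as libraries of the group with no number. Values were per kilobase of the span from transcript start to end, introns included: multiplied by this span, 99.96% and 99.95% of 4575 and 5911 low values were whole multiples of a single step, with a tolerance of 0.1 read. The recovered reads served for depth, for the filter at 100 reads and for shares of gene reads. They did not enter the tests of gene lists, since FPKM values are not counts. Reads over genes summed to 106% and 120% of the normalising totals, so some reads were counted in several rows. Among genes nested in a host of at least 10 FPKM, 3.28% of 61 on the same strand and 71.7% of 127 on the opposite strand were under 1 FPKM. Reads of nested same-strand genes, such as snoRNAs, therefore also count for the host. An exact 0 was treated as listed at 0, and whether such a gene was silent was not tested. Values of multicopy genes, histones above all, are uncertain.

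Each site was taken as the centre of its interval and set against annotated 5' ends of the authors' table. Sites within 100 bp were called at the end, those up to 500 bp near it. Lists were compared within 5 bp, with a shift of 1000 bp as background. Shares have 95% exact Clopper-Pearson intervals, which cover counting error only. Levels were analysed as log2(FPKM + 1), a scale that understates differences of low genes. The 20 gene lists were tested by the difference of medians with a two-sided permutation test over genes (100000 resamples) and by 10000 random lists matched on 10 bins of span, whose smallest p is 0.0001; both had Benjamini-Hochberg adjustment. Genes are not independent replicates, and with 2 libraries per group no test across samples was made. On simulated data for the list test over 16612 genes, 4.5% of lists without a shift had p under 0.05. With a log2 shift of 1, 30% of lists of 40 genes were recovered. Lists drawn from the 12427 genes above 0 and shifted by 2 were recovered in 100%. They were tested against all genes, those at 0 included, so this is not the recovery rate of a shift of 2.

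Named genes followed a rule fixed before the data were examined: the 10 highest in mean FPKM, the 3 highest and the lowest of each list, and the 5 with the largest difference between GRO-seq libraries among genes of at least 1 FPKM in both. Parts of the rule that need a site score or a motif could not be applied. Of 16612 accessions 16336 were found in a RefSeq gene table of a later assembly, 12347 with the same symbol; the authors' symbols were kept. Planned shares of TCT, initiator and other core promoter motifs, with the comparisons between TCT and initiator genes, need genome sequence and were not analysed here. The planned correlation of site score and FPKM was not run because the score is constant. Site calls by gene list replaced the planned test of ribosomal protein genes among TCT sites and were chosen after the data were examined. Alternatives varied distances, pseudocount, a filter at 1 FPKM, span matching, left-out libraries, list order and snoRNA reads in hosts. Computation used Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.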

Results

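Nascent RNA was profiled in Drosophila S2 cells, a line of macrophage-like character derived from late embryos. In a nuclear run-on, engaged RNA polymerases extend their transcripts with a labelled nucleotide, so that the captured RNA reports ongoing transcription. GRO-seq sequences all such RNA, and 5'GRO-seq enriches the capped fragments, whose 5' ends mark transcription starts. The 4 libraries comprised 2 of 5'GRO-seq (replicates 1 and 2) and 2 of GRO-seq, named Sample3 and Sample4 after the authors' columns. The labels do not say whether replicates came from separate cultures, so differences between them may be technical only. No treatment or genotype was contrasted. The series title concerns the TCT motif, a start-site element known from ribosomal protein promoters. Motifs at start sites were not analysed here, and the comparisons concern where transcription began, how strongly gene groups were transcribed, and how ribosomal protein genes stood among them.

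The 5'GRO-seq libraries held 13979543 reads in replicate 1 and 6710787 in replicate 2. From these the authors called 6782 and 9387 start sites, which contained 36.9% and 20.9% of the reads. The GRO-seq values covered 16612 genes. Whole reads recovered from the FPKM values put the totals behind the normalisation at 6572490 reads for Sample3 and 2474813 for Sample4. The median gene had 26 reads in Sample3 and 7 in Sample4, and 4185 genes were listed at 0 in both.

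Start sites of replicate 1 lay mostly at the 5' ends of annotated genes, whereas in replicate 2 the largest class was sense gene bodies. Of the replicate 1 sites, 3978 of 6782 (58.7%, 95% exact Clopper-Pearson interval 57.5 to 59.8%) lay within 100 bp of an annotated 5' end on the same strand. In replicate 2 the number was 2391 of 9387 (25.5%, 24.6 to 26.4%). Sites inside genes on the sense strand, more than 500 bp from the 5' end, made up 5.29% (4.77 to 5.85%) of replicate 1 and 33.4% (32.5 to 34.4%) of replicate 2. Intervals here cover counting error only.

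On the opposite strand, sites within 100 bp of an annotated 5' end made up 5.06% of replicate 1 and 1.94% of replicate 2. Antisense sites near 5' ends formed 8.68% and 3.74% of the lists, and antisense sites in gene bodies 7.27% and 7.69%. Sites outside annotated genes accounted for 16.6% of replicate 1 and 25.2% of replicate 2. Heterochromatic and unplaced sequence held 2.71% and 6.15% of the sites.

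**Figure D1:**
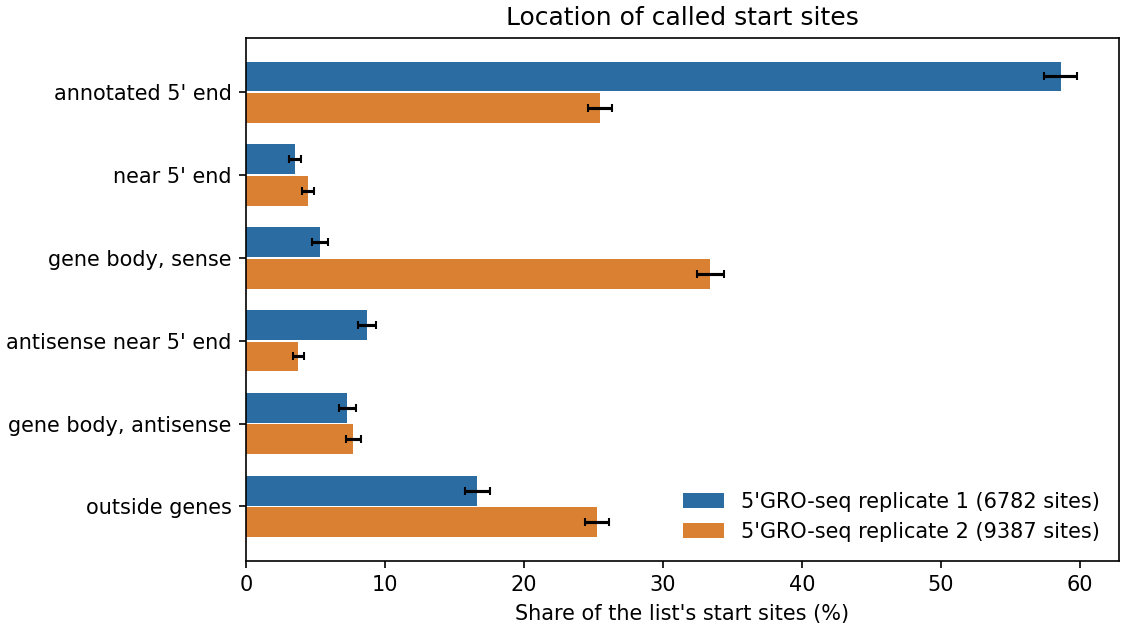
Share of called start sites (%, horizontal axis) by location relative to annotated genes for the 2 5'GRO-seq replicates; error bars are 95% exact binomial intervals. Replicate 1 had 58.7% of its sites at annotated 5' ends and replicate 2 had 25.5%, while sense gene bodies held 5.29% and 33.4%.

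Sites at annotated genes lay mostly just downstream of the annotated 5' end. Among sites within 100 bp of an annotated 5' end, the median position was 6 bp downstream in replicate 1 (quartiles 2 and 24 bp) and 7 bp downstream in replicate 2 (quartiles 2 and 28 bp). Of these sites, 81.9% and 80.9% were downstream of it, and 51.01% and 46.80% were within 10 bp. PCNA, the sliding clamp of DNA replication, had its site exactly at the annotated base in both lists. Further examples with the same site in both lists were EF2, a translation elongation factor, at 4 bp, and the receptor tyrosine kinase antagonist sty at 2 bp. Ef1gamma, a subunit of elongation factor 1, was an exception, with its site 86 bp upstream of the annotated end in both lists.

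**Figure D2:**
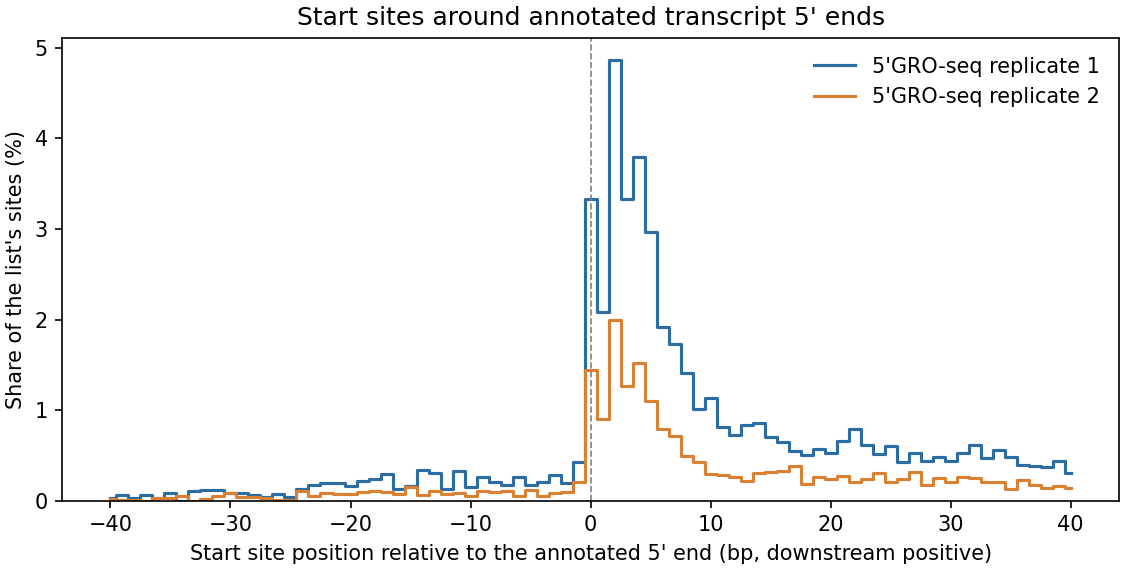
Position of start sites relative to the nearest annotated 5' end on the same strand (bp, downstream positive, horizontal axis) as a share of all sites in each list (%, vertical axis), one line per 5'GRO-seq replicate. Both lines rise at the annotated end, with medians of 6 and 7 bp downstream for sites within 100 bp.

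The lists shared a core of promoter sites. Within 5 bp on the same strand, 1796 sites were found in both lists, 26.5% (25.4 to 27.5%) of replicate 1 and 19.1% (18.3 to 19.9%) of replicate 2. After a shift of one list by 1000 bp, the shares were 0.103% and 0.0426%. Of the shared sites 1621 lay at the same base, and 70.6% (68.4 to 72.7%) were at annotated 5' ends. In replicate 2, 53.0% of the sites at annotated 5' ends were shared, against 2.30% of those in sense gene bodies. Counted over 13939 protein-coding genes, 1737 had a site in both lists, 2235 in replicate 1 alone and 626 in replicate 2 alone.

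The composition of the lists changed with file order. Neither list carries a score, but the file order of sites at the same base correlated between the lists (Spearman's rho 0.820 across 1621 sites, which are not independent replicates). In the leading 1000 sites, 74.2% of replicate 1 and 60.1% of replicate 2 lay at annotated 5' ends, and 3.10% and 11.5% lay in sense gene bodies.

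**Figure D3:**
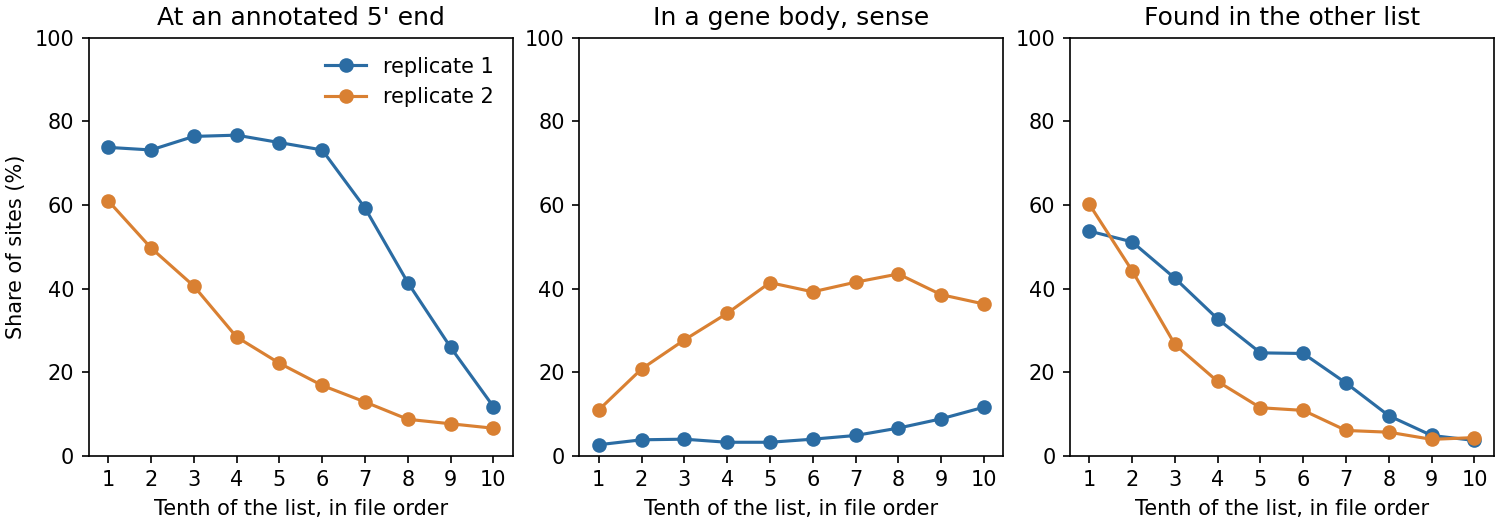
Share of start sites (%, vertical axes) at annotated 5' ends, in sense gene bodies and found in the other list, by position in the file in 10 equal parts (horizontal axis), for 5'GRO-seq replicates 1 and 2. At annotated 5' ends the share goes from 73.8% to 11.8% in replicate 1 and from 61.0% to 6.60% in replicate 2.

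The GRO-seq libraries ranked genes alike, but their values differed by more than counting error. Small nucleolar RNAs, which guide modification of ribosomal RNA, were mostly lower in Sample4. Across 16612 genes, log2(FPKM + 1) had a Pearson correlation of 0.963 and a Spearman correlation of 0.943; genes are not independent replicates. Over 8417 genes with at least 1 FPKM in both, Pearson's r was 0.907, and the SD of the log2 difference was 0.73. For 3604 genes with 100 or more reads in both, this SD was 0.63, against a median of 0.105 from counting error alone. For the 3443 protein-coding genes among them it was 0.54. Of 244 snoRNA genes with at least 1 FPKM in both, 234 were lower in Sample4, with a median log2 difference (Sample4 minus Sample3) of -2.27. Over all 273 snoRNA genes, the median FPKM was 672.5 in Sample3 and 131 in Sample4.

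Small noncoding RNAs had the highest values per kilobase of span, although protein-coding genes held 89.1% and 93.0% of the gene reads in Sample3 and Sample4. The 10 genes with the highest mean FPKM comprised 9 snoRNAs and snRNA:7SK, the RNA that holds the elongation factor P-TEFb inactive. snRNA:7SK stood at 4603 FPKM in Sample3 and 38484 in Sample4, and snoRNA:Me28S-G3081a at 26969 and 10375 FPKM. The 5 largest differences between the libraries were in small RNAs, led by snoRNA:Me28S-A982a with 893 and 47.9 FPKM. Among protein-coding genes, chosen after their values were seen, RpL23A differed from 368 to 2169 FPKM, and CG34034 from 28.4 to 2.11 FPKM.

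Cytoplasmic ribosomal protein, respiratory chain, proteasome and translation factor genes stood furthest above other genes in nascent RNA level, in the test against all other genes. Below the ribosomal protein and respiratory chain lists, this order changed among genes of at least 1 FPKM and against span-matched lists. Cytoplasmic ribosomal protein genes had medians of 428 FPKM in Sample3 and 559 FPKM in Sample4, and all 79 were above the median of the other genes. Their median exceeded that of the other genes by 7.52 on the log2(FPKM + 1) scale. Of the 20 gene lists fixed before the data were examined, 12 were higher than the remaining genes, 0 were lower and 8 did not pass the threshold. The smallest unadjusted p among lists below the other genes was 0.0645 (permutation test), for the 49 fat body and gut markers. Their median was 0, the lowest value possible, so lists of that size or smaller could not come out lower in this test. The test was a two-sided permutation test over genes with 100000 resamples and Benjamini-Hochberg adjustment over the lists. Against random lists matched on transcript span, 11 lists were higher and 2 lower.

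Among ribosomal protein genes, RpLP1 of the ribosomal stalk had the highest mean, 2536 ± 1815 FPKM (SD, n = 2). RpS26 had 1535 ± 470 FPKM (SD, n = 2), and RpL38 had the lowest mean of the list, 86.7 ± 69.0 FPKM (SD, n = 2). The adjusted p of the list was 4e-05 by the permutation test, whose raw p of 1e-05 was the smallest possible. RpL3 had 1906 ± 1304 FPKM (SD, n = 2), but its introns hold snoRNAs: without their reads it had 325 FPKM in Sample3 and 175 in Sample4. Such hosts made up 28 of the 79 genes, and without snoRNA reads the list medians were 325 FPKM and 470 FPKM. The 14 ribosomal protein duplicates, such as RpL34a with 104 ± 85.9 FPKM (SD, n = 2), differed from other genes by 0.37 (adjusted p = 0.858, permutation test), and RpS28a was listed at 0.

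Translation factors were higher by 3.86 (adjusted p = 4e-05, permutation test), with 38 of 43 above the median of other genes. Ef1alpha48D, which delivers aminoacyl-tRNA to the ribosome, had 1613 ± 657 FPKM, EF2 567 ± 121 FPKM and Ef1gamma 378 ± 190 FPKM (SD, n = 2), whereas eIF4E-4 was listed at 0. Ribosome assembly and RNA polymerase I genes were higher by 3.09 (adjusted p = 6.7e-05, permutation test), all 22 above that median, led by Non1 with 182 ± 43.1 FPKM. All 22 aminoacyl-tRNA synthetases were above it too, by 3.20 (adjusted p = 8.6e-05, permutation test), led by Aats-ala with 59.1 ± 1.65 FPKM. Against span-matched lists the synthetases did not pass (adjusted p = 0.0587, random-list permutation test). Mitochondrial ribosomal protein genes were higher by 2.07 (adjusted p = 0.00036, permutation test), all 75 above the median of other genes. Their medians were 10.4 FPKM in each library, and among genes of at least 1 FPKM they stood at -0.25 (adjusted p = 0.205, permutation test).

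Respiratory chain and ATP synthase genes were higher by 4.51 (adjusted p = 4e-05, permutation test), all 23 above the median of other genes. ATPsyn-gamma led them with 178 ± 41.7 FPKM and sun was lowest with 16.9 ± 5.14 FPKM (SD, n = 2). Proteasome genes were higher by 3.86 and heat shock and chaperone genes by 3.39 (each adjusted p = 4e-05, permutation test). Rpn7 of the proteasome lid had 67.5 ± 13.8 FPKM, and 33 of the 47 proteasome genes were above the median of other genes. A further 12, Rpt4R among them, were listed at 0. Hsc70-4, a constitutive chaperone, had 509 ± 99.8 FPKM and Hsp83 424 ± 15.9 FPKM (SD, n = 2).

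RNA polymerase II and general factor genes were higher by 2.58 (adjusted p = 0.00055, permutation test), with 29 of 31 above the median of other genes. All 33 cell cycle and replication genes were above it, by 2.55 (adjusted p = 0.00054, permutation test), led by the Cdc25 phosphatase gene stg with 174 ± 2.19 FPKM and PCNA with 70.6 ± 4.54 FPKM. Among genes of at least 1 FPKM neither list passed (adjusted p = 0.238 and 0.386, permutation test), and the cell cycle list did not pass against span-matched lists (adjusted p = 0.109, random-list permutation test). Replication-dependent histones were higher by 1.51 (adjusted p = 0.010, permutation test), but 80 of 111 rows had spans over 100000 bp and only 22 distinct pairs of values occurred. The call was lost with a pseudocount of 0.1 (2.03, adjusted p = 0.0572, permutation test), and among genes of at least 1 FPKM the list was lower (-0.77, adjusted p = 0.0001, permutation test).

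Immune pathway genes were higher by 2.72 (adjusted p = 0.00027, permutation test), with 27 of 31 above the median of other genes; among genes of at least 1 FPKM the difference was 0.68 (adjusted p = 0.0358, permutation test). Rel, an NF-kappaB factor of the immune response, had 76.36 ± 28.99 FPKM, and the antifungal peptide gene Drs had 64.2 ± 1.02 FPKM (SD, n = 2). Dpt, the lowest of the list, had 0.15 ± 0.22 FPKM (SD, n = 2). The 30 markers of hemocytes, the blood cells of the fly, did not pass as a list (1.36, adjusted p = 0.167, permutation test), nor against span-matched lists (0.66, adjusted p = 0.525, random-list permutation test). They passed among genes of at least 1 FPKM (1.20, adjusted p = 0.0020, permutation test), a filter on the tested value that left 24 of the 30. In this list the collagen gene Cg25C had 569 ± 415 FPKM and the laminin gene LanB1 178 ± 9.52 FPKM. Signalling targets stood at 1.78 (adjusted p = 0.059, permutation test), with sty at 152 ± 42.3 FPKM. The list passed without Sample3 (adjusted p = 0.0191, permutation test) and against span-matched lists (1.84, adjusted p = 0.020, random-list permutation test). It also passed among genes of at least 1 FPKM (1.07, adjusted p = 0.0063, permutation test), where 22 of 30 members were left. It did not pass without Sample4 (1.45, adjusted p = 0.1455, permutation test) or with a pseudocount of 0.1 (2.31, adjusted p = 0.184).

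The lists of Hox and segmentation genes and of neuron, muscle, germline, and fat body and gut markers did not pass the test against all other genes. At their sizes, the main setting of this test could not call them lower. Hox and segmentation genes stood at -1.18, neuron markers at -1.25, muscle markers at -1.25 and germline markers at -0.18 (adjusted p = 0.290, 0.377, 0.307 and 0.918, permutation test). Against span-matched lists Hox and segmentation genes were lower by a difference of -1.98 and muscle markers by -1.97 (adjusted p = 0.0096 and 0.020, random-list permutation test). Fat body and gut markers stood at -1.42 (adjusted p = 0.092, permutation test), with 28 of 49 listed at 0 in both libraries; the list passed without Sample4 (adjusted p = 0.0414) and with a pseudocount of 0.1 (-4.06, adjusted p = 4e-05). Germline markers passed among genes of at least 1 FPKM (-1.58, adjusted p = 0.0038, permutation test), where 13 of 19 members were left. The highest of the neuron markers, the RNA-binding protein gene elav, had 10.1 ± 0.0424 FPKM (SD, n = 2). The list medians were 0.163 FPKM in Sample3 and 0.122 in Sample4. Highest of the germline markers was tud with 37.0 ± 2.89 FPKM (SD, n = 2), against list medians of 1.43 and 1.42 FPKM.

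**Figure D4:**
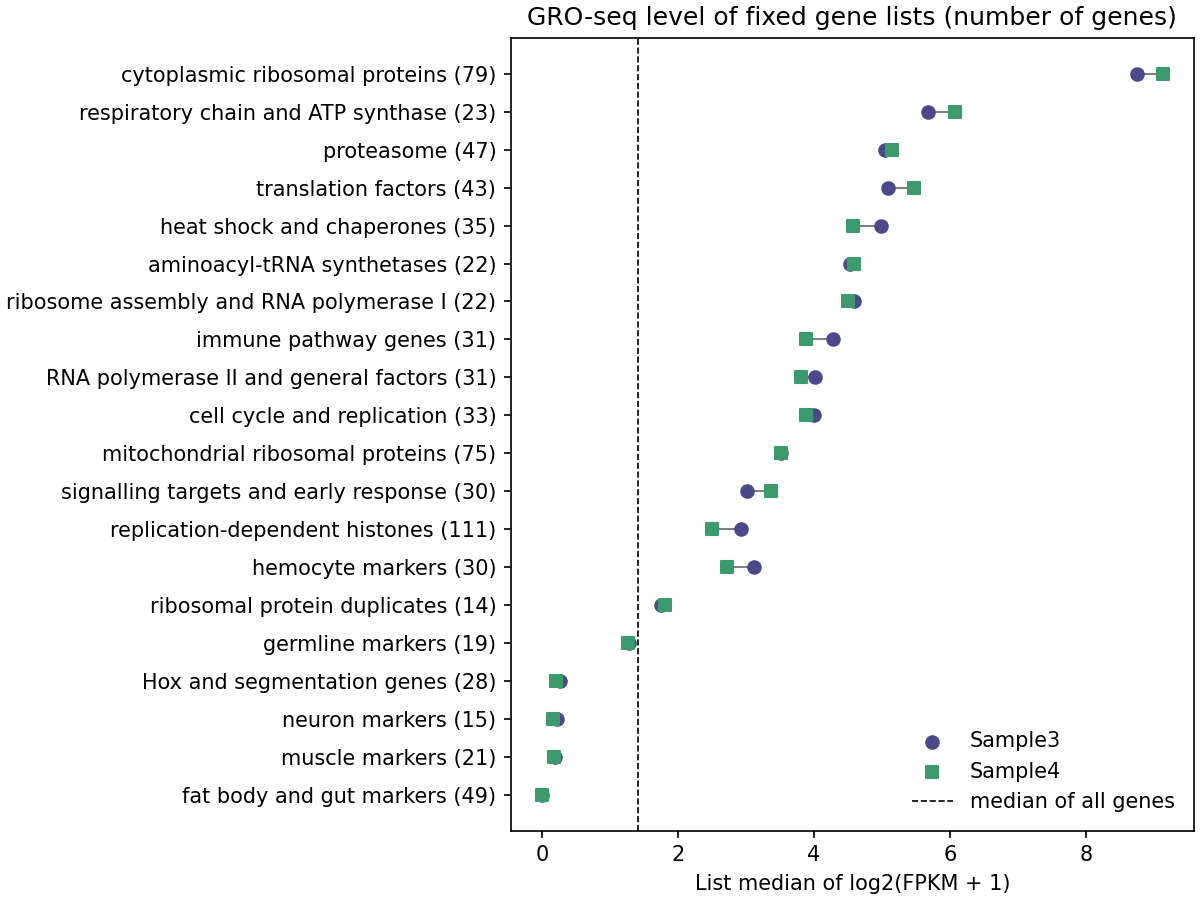
Median log2(FPKM + 1) of each of the 20 gene lists (horizontal axis) in the GRO-seq libraries Sample3 (circles) and Sample4 (squares), with list sizes in parentheses and the median of all genes as a dashed line. Cytoplasmic ribosomal protein genes lie farthest right, with 7.52 over the other genes.

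Ribosomal protein genes more often carried a called start site than other transcribed genes in replicate 1, and in both lists the site was more often within 10 bp of the annotated 5' end. In replicate 1, 57 of 79 (72.2%) had a site within 100 bp, against 42.6% of the other genes with mean FPKM of at least 1 (odds ratio 3.495, adjusted p = 1.4e-06, two-sided Fisher's exact test over 20 lists). In replicate 2 the shares were 36.7% and 26.2%, which did not pass (odds ratio 1.64, adjusted p = 0.215, Fisher's exact test). Sites of the lists within 5 bp of each other were present at 26 of 79 (32.9%) against 13.7% (odds ratio 3.08, adjusted p = 0.0002, Fisher's exact test). These comparisons of site calls by gene list were chosen after the data were examined.

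The ribosomal protein sites were tightly placed. Placement was compared for the ribosomal protein list alone and was not among the planned tests. In replicate 1, 48 of 57 (84.2%) lay within 10 bp of the annotated end, against 48.8% at other genes (odds ratio 5.60, unadjusted p = 5.5e-08, two-sided Fisher's exact test). In replicate 2 the shares were 79.3% and 45.4% (odds ratio 4.62, unadjusted p = 0.00026, Fisher's exact test). The median offsets, 5 bp against 7 bp in replicate 1, did not differ by a two-sided permutation test (p = 0.512). A site in each list within 100 bp of the annotated end, whatever their distance from each other, was present at 28 ribosomal protein genes. Of these, 24 (85.7%) had both at the same base, against 66.1% of 1739 other genes (unadjusted p = 0.0274, Fisher's exact test). The other genes were not matched on level. In dm3 coordinates, RpS26 (2L, 18442507 to 18443228, minus strand) started at 18443223 in both lists, 5 bp inside the annotated end. RpL23A (3L, 1667192 to 1668654, minus strand) started at 1668651 and RpS13 (2L, 8363699 to 8364596, minus strand) at 8364593 in both. RpLP1 and RpL3 had a site in replicate 1 alone, at 5 bp and 3 bp. No site was called at 21 of the 79 genes, RpL17 and RpL28 among them. A call required 4-fold over the GRO-seq control, so a missing call does not show that a start was absent. RpL17, RpL28 and RpS13 were named after their values were seen.

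A further 3 lists had a higher rate of calls in replicate 1. Among members with mean FPKM of at least 1, a site was called at 54 of 75 mitochondrial ribosomal protein genes (adjusted p = 2.8e-06, Fisher's exact test), at 24 of 33 proteasome genes (adjusted p = 0.0031) and at 16 of 22 ribosome assembly and RNA polymerase I genes (adjusted p = 0.0319). For sites found in both lists, ribosome assembly and RNA polymerase I genes passed (40.9%, adjusted p = 0.0113, Fisher's exact test), whereas mitochondrial ribosomal protein genes (14.7% against 13.9%, adjusted p = 1) and proteasome genes (adjusted p = 0.600) did not. With the replicate 2 list 0 gene lists were higher after adjustment, although ribosomal protein genes (p = 0.0397) and proteasome genes (p = 0.0458) had an unadjusted Fisher's exact p under 0.05. Histone rows, many of which repeat a single long span, could not be assessed for start sites. Called genes were transcribed at a median log2(FPKM + 1) of 3.77 in replicate 1, against 0.30 for genes without a site. Over all gene classes, calls did not rise steadily with level. With genes of at least 1 FPKM in 10 equal bins, the replicate 1 share peaked at 54.5% in bin 7. It was 38.6% in bin 10, which also held noncoding genes such as snoRNAs. Protein-coding genes of bin 10 were called more often, 57 of 79 ribosomal protein genes (72.2%) and 263 of 532 others (49.4%). The other bins were not split by class.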

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

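The tests on the composition of the replicate 2 list were chosen after the result was seen. Start sites on the mitochondrial genome, which the comparisons did not use, numbered 6 in replicate 1 (0.0885% of its sites) and 22 in replicate 2 (0.234%). The criterion, more than the 3 that a count of 0 allows, says nothing about how many were to be expected. Mitochondrial transcripts are not capped, and no explanation of these sites was tested on them.

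The replicate 2 list lay less often at annotated 5' ends, 25.5% against 58.7%, and more often in sense gene bodies. Lower depth of the replicate 2 5'GRO-seq library alone is argued against, on the assumption that file order follows site strength. Among the leading 1000 sites of its list, 11.5% (9.59 to 13.6%) lay in sense gene bodies, against 3.10% (2.12 to 4.37%) in replicate 1. The GRO-seq libraries also differed in depth, and their part as controls is not addressed by this comparison. Starts missed by the annotation stay open. Of the 115 leading gene-body sites, 22 (19.1%, 12.4 to 27.5%) were found in replicate 1. Of the 601 leading sites at annotated 5' ends, 71.2% (67.4 to 74.8%) were. A low shared share of gene-body sites follows, however, from replicate 1 holding fewer of them, so it decides nothing. Uncapped RNA left in replicate 2 cannot be told apart from the different GRO-seq controls: at snoRNA 5' ends, which processing leaves uncapped, 35 genes had a site in replicate 2 alone and 1 in replicate 1 alone, but snoRNA values also differed between the GRO-seq libraries, and among 34 snoRNAs within 2-fold there the numbers were 2 and 0 (p = 0.50, two-sided exact McNemar test, the smallest that 2 genes allow). Missed starts, uncapped RNA and the controls stay open, and no biological explanation was tested, since both libraries have the same label.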

How the results depend on the processing

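The settings by file order, snoRNA reads and all those for site calls by list were chosen after seeing the data. Of 145 alternative values, 109 kept their direction and side of the threshold or, for counts of lists, stayed close to the main count. The cause of the others was not tested unless stated. The share of replicate 1 sites found in replicate 2 (26.5%) was 23.9% at 0 bp, 30.1% at 20 bp, 35.99% at 100 bp, by construction of a wider window, and 39.0% in the leading part (50% of sites) of each list. Sites at annotated 5' ends went from 58.7% to 53.8% at 50 bp, 60.6% at 250 bp, 70.6% among shared sites and 74.99% in the leading part for replicate 1, and from 25.5% to 22.35%, 27.9%, 70.6% and 40.4% for replicate 2. Pearson's r between GRO-seq libraries (0.963) was 0.959 with a pseudocount of 0.1 and 0.907 for genes of at least 1 FPKM in both. The number of higher lists, 12, ranged from 10 to 13, though not always with the same lists. Among genes of at least 1 FPKM, signalling targets and hemocyte markers entered, while RNA polymerase II and cell cycle genes were among those that left. This filter acts on the tested value, so low members and low other genes drop out. The number of lower lists, 0, was 1 with a pseudocount of 0.1, 2 among genes of at least 1 FPKM, 2 against span-matched lists, and 0 to 1 when a library was left out. The ribosomal protein difference ranged from 5.21 to 8.23 and passed in all 6 alternatives run. A pair of lists turned direction among genes of at least 1 FPKM, mitochondrial ribosomal proteins at -0.25 and histones at -0.77. Germline markers, which did not pass, ranged from -0.29 to 0.025 when a library was left out. The odds ratio for sites at ribosomal protein genes, 3.495, was 1.64 with the list of replicate 2 (adjusted p = 0.215, Fisher's exact test; 3.5e-08 to 0.215 over the alternatives) and 2.65 against other protein-coding genes in the highest of 10 level bins (adjusted p = 0.0019, Fisher's exact test). No paired analysis was possible because the GRO-seq columns carry no replicate number. Alternatives by score, motif window or TCT class were not run, for want of scores and sequence, and choices between transcripts change nothing with 1 transcript per gene. Median depth of 7 reads per gene in Sample4 limits the values of low genes.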

Other observations

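The tests on snoRNA values were chosen after the result was seen. For ribosomal protein sites, the prediction for the highest level bin was written before that test, whereas the placement comparison itself was not planned. Start sites at gene promoters often had a partner on the opposite strand. Of 3978 replicate 1 sites at annotated 5' ends, 1421 (35.7%, 34.2 to 37.2%) had an opposite-strand site within 1000 bp upstream, against 3.52% downstream and 4.93% after shifting the sites by 5000 bp. Most partners, 1088, lay at the annotated end of another gene, and 333 (8.37% of the sites) did not. In replicate 2 the upstream share was 20.3%, against 5.48% after the shift, but partners away from annotated ends were at 4.85% against 3.85% after the shift. Among sites found in both lists the upstream share was 8.60%, against 1.74% after the shift. A partner away from annotated ends was present at 1.34%, against 0.631% after the shift. The backgrounds were lower here too, so these shares are not comparable with those of the single lists.

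GRO-seq values of snoRNAs were lower in Sample4, with a median log2 difference of -2.27 (bootstrap 95% interval -2.40 to -2.14). Whether they came from nascent or mature RNA was not tested. Lower transcription of the host genes is argued against: 76 hosts differed by -0.079 (-0.23 to 0.15) once snoRNA reads were taken away. Loss of short spans cannot be told apart from a loss of snoRNAs: 141 other genes of at most 300 bp differed by -0.55, but the 23 snRNAs among them by -1.64 and the 110 ncRNAs by -0.48. RNA handling that loses mature small RNA stays a possible explanation, untested here, and snRNA:7SK went the other way, 4603 against 38484 FPKM. The labels name no biological difference between the libraries, and none other than host transcription was tested.

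Start sites of ribosomal protein genes lay within 10 bp of the annotated end more often than those of other genes. Of 263 other protein-coding genes with a site in the highest of 10 level bins, 55.9% had it within 10 bp. Among 57 ribosomal protein genes the share was 84.2% (odds ratio 4.21, unadjusted p = 4.4e-05, two-sided Fisher's exact test). Being in the highest bin thus did not account for the difference. That bin had a median of 112.57 FPKM, below the ribosomal protein medians of 428 and 559 FPKM. Better annotation of the most strongly transcribed genes therefore stays a possible cause. A more focused start at these promoters is a hypothesis that remains open, and the TCT motif could not be tested without sequence. Better annotation of ribosomal protein genes in particular was not tested.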
